A study of Mus musculus with 20 samples.

How the data were processed

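The labels describe 20 mouse ChIP-seq samples. GPS2, a subunit of the N-CoR and SMRT corepressor complexes, was the target in 6 of them, H3K9me3 in 6 and RNA polymerase II in 4, and 4 were input DNA. Peak lists of 4 GPS2 samples were analysed: 3T3-L1 cells (a mouse preadipocyte line) without treatment and with FCCP, which uncouples mitochondrial respiration, and brown adipose tissue (BAT) of male and of female wild-type mice. The other 16 samples had no list of their own in this comparison; among them, the GPS2 libraries of knockout BAT entered as the background of the BAT lists, and the rest were not analysed here. The sex of the BAT samples is that of their own labels, although the growth protocol in the labels speaks of male animals throughout.

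Reads were mapped to mm8 with Bowtie2 or Bowtie and peaks were called with HOMER, per the submitters' processing notes; versions were not given in the sources used here. Each 3T3-L1 list was called on 1 pool of 2 libraries without a control, per the file headers, with a false discovery rate of 0.001, at least 4-fold over the surrounding 10000 bp and at most 3 tags per base pair. Each BAT list was called on 1 wild-type library against the knockout library of the same sex, per the file headers, with a rate of 0.05, at least 2-fold over the knockout, at least 2-fold over the surroundings and at most 1 tag per base pair. The cell and tissue lists therefore rest on different rules.

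The deposited normalized tag count is a signal, the tags in a peak scaled to a library of 10000000 tags; these are called normalized tags. The deposited score is HOMER's tag score, and folds over the local region and over the knockout are ratios; all of these are the authors' values for single peaks. The deposited total tag count of male peaks, the knockout tags, the focus ratio (a fraction) and the p-value columns entered no comparison, except that the knockout tags of female peaks gave the counting error of a fold. The knockout tags are also given for the tallest female peaks. The column on clonal tags was not used here.

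The libraries held 74504840 tags for untreated and 66979291 for FCCP-treated cells, 30069322 for male and 39310667 for female BAT. A peak of median height held about 29.0, 27.0, 13.0 and 13.0 tags in these lists, so that counting error alone was 18.6%, 19.2%, 27.7% and 27.7% of its height. There was 1 list per condition, so no difference has a replicate check and no p-value is given for the change of a peak.

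Peaks on the assembled autosomes, X and Y were compared, with positions read as 1-based and closed intervals. Peaks that shared at least 1 bp were counted as overlapping (bedtools 2.31.1). Shares carry Wilson 95% intervals, which cover counting error only and treat peaks as independent. Chance overlap was the mean over 100 random circular shifts of a list along each chromosome. At shared peaks, the log2 ratio of normalized tag counts was taken over pairs with the longest overlap. Ratios of single peaks carry exact 95% intervals from the tags of the libraries compared. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

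The overlap and ratio steps were tested on simulated data. For FCCP against untreated cells, a planted share of 40% over 44479 peaks was found as 40.5%, and a planted log2 ratio of 0.26 as 0.26. For male against female BAT, a planted share of 10% over 19121 peaks was found as 10.5%, and a planted log2 ratio of -0.32 as -0.35. Planted peaks were moved by less than a peak width and no call threshold was applied. The simulation therefore checks the code only, not the overlap lost near thresholds.

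The overlap shares, the ratio of tag counts at shared FCCP and untreated peaks, the alternative settings listed here and the rule for named peaks were fixed before the data were examined. The ratios of peak numbers, the ratio of tag counts at shared male and female peaks, the overlap by peak height, the counts by chromosome and region and the window correlations were added afterwards, as were the alternatives named as such. The rule names 5 peaks each for the highest tag counts in either list alone, the largest and smallest ratios among shared peaks above the median height, and the highest shared tag counts. Alternatives were peak centres within 200 bp, 50% of the shorter peak, stricter folds, equal numbers of top-scoring peaks and all sequence names. Results on promoters, genes and gene lists were planned for an annotation of the build of the files, which was not used here: the gene table at hand is on GRCm38.p6, and positions were not converted between builds. Peaks are therefore named by mm8 position.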

Results

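GPS2 occupancy was compared between untreated and FCCP-treated 3T3-L1 cells, and between brown adipose tissue of male and female mice, where the knockout library of the same sex served as the background. The lists held 44636 peaks for untreated cells, 60481 for FCCP, 40040 for male BAT and 19150 for female BAT. Of these, 44505, 60313, 39978 and 19122 lay on the assembled autosomes, X and Y. Peaks took 2.00% of the tags in untreated cells, 2.77% after FCCP, 1.91% in male and 1.03% in female BAT.

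The first comparison asks how GPS2 binding differs once mitochondria are uncoupled. The FCCP list was 1.36 times as long as the untreated list, and it was longer on each of the 19 autosomes, from 1.29 times on chromosome 5 to 1.50 times on chromosome 12. The X chromosome had 3104 peaks after FCCP and 1993 without, a ratio of 1.56. Among taller or better isolated peaks the ratio was not smaller: it was 1.49 for peaks of at least 7 normalized tags and 1.61 for peaks at least 8-fold over their surroundings. Both of these limits were chosen after the lists had been seen.

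Of the untreated peaks, 18528 of 44505 overlapped an FCCP peak (41.6%, Wilson 95% interval 41.2 to 42.1). Of the FCCP peaks, 18529 of 60313 overlapped an untreated peak (30.7%, 30.4 to 31.1). Circular shifts gave 1.32% and 0.970%. Shared peaks were taller than the others: their median was 4.63 normalized tags in the FCCP list, against 3.88 for the 41784 FCCP peaks without an untreated partner. In the tallest 10%, 73.8% of untreated and 63.6% of FCCP peaks overlapped the other list, and in the lowest 10% 25.3% and 16.7%.

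**Figure D1:**
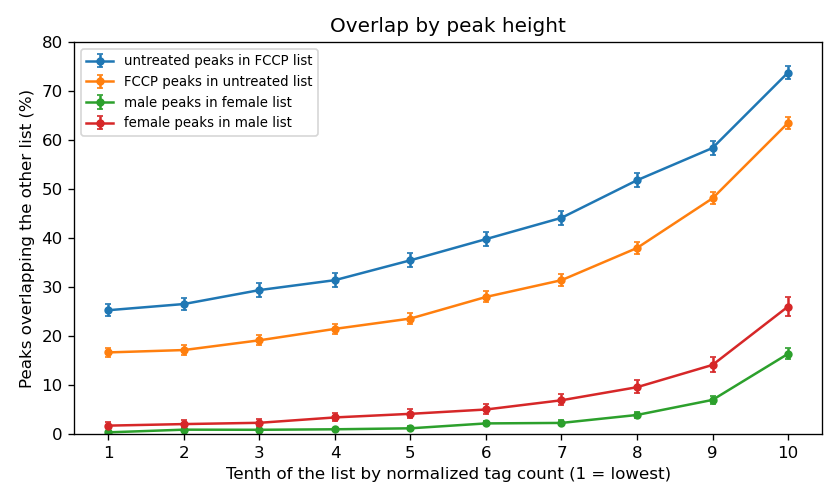
Share of peaks (%) that overlap the other list, in 10 equal parts of each list ranked on normalized tag count; points are shares and bars Wilson 95% intervals. The share rises from 25.3% to 73.8% for untreated peaks and from 1.73% to 26.0% for female BAT peaks.

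At the 18528 shared pairs, tag counts after FCCP were close to those without: the median log2 ratio was 0.08, with quartiles of -0.09 and 0.25. The SD of the log2 ratios was 0.26, below the 0.36 that counting error gives for peaks of this height; shared peaks had passed a threshold in both lists. FCCP was higher at 61.2% of pairs. The log2 ratio was above 1 at 6 pairs and below -1 at 1 pair.

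The tallest shared peaks lay on chromosome 2 (98467867 to 98468127), chromosome 14 (39187523 to 39187783 and 18209878 to 18210138), chromosome 9 (35054926 to 35055186) and chromosome 12 (3109866 to 3110126). The chromosome 2 peak had 223.5 normalized tags after FCCP and 215.3 without, a ratio of 1.04 (exact 95% interval 0.967 to 1.11). For all 5, the interval of the ratio included 1. Both lists were called without a control, so height alone does not show GPS2 binding. Ratios near 1 at these peaks therefore need not mean stable GPS2 occupancy.

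The largest ratio above the median height was at chromosome 15, 63402598 to 63402858, with 8.96 against 3.76 normalized tags (2.38-fold, 1.50 to 3.88). It was followed by chromosome 1, 124435579 to 124435839 (2.27-fold), chromosome 9, 83836087 to 83836347 (2.15-fold), chromosome X, 41294537 to 41294797 (2.14-fold) and chromosome 7, 7057955 to 7058215 (2.04-fold). The smallest were at chromosome 1, 178618666 to 178618926 (0.497-fold, 0.297 to 0.809) and 14804929 to 14805189 (0.502-fold), chromosome 19, 32888935 to 32889195 (0.504-fold), chromosome 10, 23958606 to 23958866 (0.518-fold) and chromosome 13, 14405091 to 14405351 (0.540-fold). These are the extremes of 18528 pairs, and their intervals are not adjusted for that choice.

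The tallest peaks of either list without an overlapping partner often had a near one. The FCCP peak at chromosome 13, 74995953 to 74996213 (52.3 normalized tags) lay 462 bp, centre to centre, from an untreated peak at 74996413 to 74996677 (47.9). On chromosome 4, the FCCP peak at 3017134 to 3017394 (37.5) lay 477 bp from the untreated peak at 3016655 to 3016919 (36.2). The tallest FCCP peak without a partner, at chromosome 17, 13343369 to 13343629, had 60.9 normalized tags and lay 1178 bp from an untreated peak. The others were at chromosome 2, 77764005 to 77764265 and 77784545 to 77784805, each with 32.1. In untreated cells the others were at chromosome 18, 3005683 to 3005947 (29.9), chromosome 6, 47666823 to 47667087 (24.7) and chromosome 5, 16981760 to 16982024 (22.4).

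A stretch of chromosome 1 from 140 to 150 Mb, chosen after its values were seen, held 909 untreated and 937 FCCP peaks. The median of the other 19 windows of this size on the chromosome was 176 and 261. In BAT the same stretch held 72 male and 36 female peaks, against medians of 165 and 68.

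**Figure D2:**
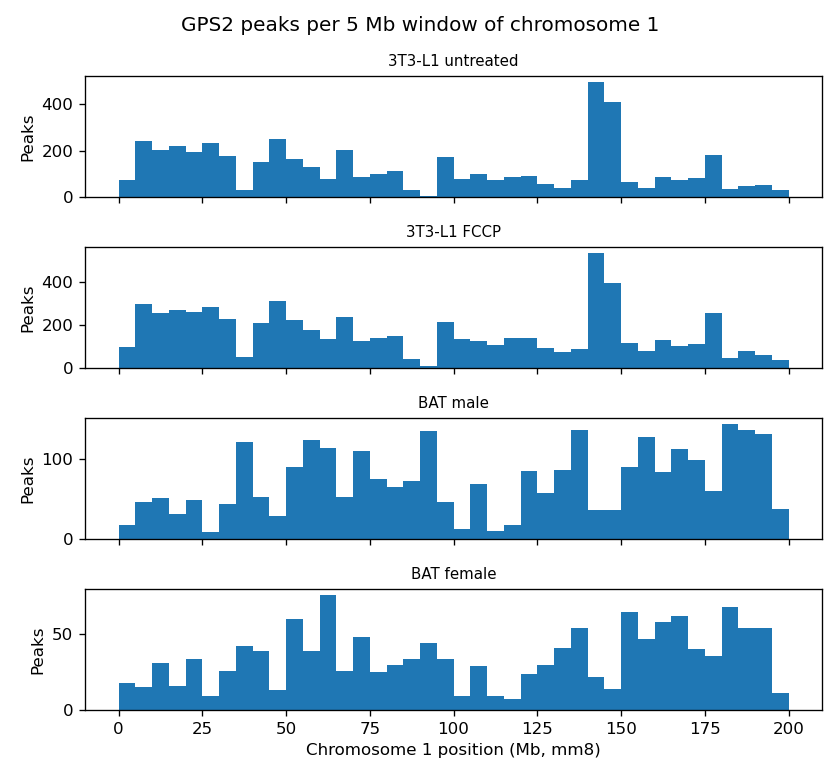
Number of GPS2 peaks in each 5 Mb window of chromosome 1 (mm8) for the 4 lists, with a separate vertical scale for each. Both 3T3-L1 lists pile up between 140 and 150 Mb, with 909 and 937 peaks, and the BAT lists do not.

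The next comparison sets male against female BAT, with the sex as each sample is labelled; the growth protocol in the labels speaks of male animals throughout, so the labels are at odds. The list labelled male had 5 peaks on Y and 27 on unplaced Y sequence, and the list labelled female 1 and 1. Local tag density around X peaks was 0.459 times the autosomal median in the list labelled male and 0.610 times in the other. The male list was 2.09 times as long, and among the autosomes the ratio ran from 1.88 on chromosome 3 to 2.34 on chromosome 5. The X chromosome had fewer peaks in males (324) than in females (399). The ratio rose to 7.72 for peaks of at least 5 normalized tags, and was 1.79 for peaks at least 4-fold over knockout, both limits chosen after the lists had been seen. The median peak held 13.0 tags in both lists, which is 4.32 normalized tags in males and 3.31 in the deeper female library. A limit in normalized tags thus asks for more tags in the female list, as scaling to depth requires. The tag thresholds of the calls were close on this scale, at 2.66 normalized tags in males and 2.54 in females. How far depth contributes to the 7.72 was not tested. Few peaks were shared: 1439 of 39978 male peaks overlapped a female peak (3.60%, 3.42 to 3.79), and 1439 of 19122 female peaks a male one (7.53%, 7.16 to 7.91). Circular shifts gave 0.213% and 0.450%. The shares depended on the peaks taken: with equal numbers of top-scoring peaks both were 9.95%, and at least 4-fold over knockout they were 1.80% and 3.23%. Chance overlap was 0.114% and 0.109% at the first of these settings, and 0.197% and 0.354% at the other. In the tallest 10% the shares were 16.4% and 26.0%. Shared peaks had lower median folds over knockout than the others, 3.83 against 5.53 in males and 5.09 against 6.02 in females. The knockout rule had removed 75.6% of male and 83.6% of female putative peaks before the lists were compared. A missing partner therefore need not mean a lack of signal in the other library.

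At the 1439 shared pairs, male tag counts were higher at 95.3%, with a median log2 ratio of 0.62 and quartiles of 0.38 and 0.92. With 1 library per sex, this compares the libraries, not the sexes. The tallest shared peak, at chromosome 9, 95235259 to 95235393, had 511.2 normalized tags in males and 423 in females (1.21-fold, 1.13 to 1.30). The next were at chromosome 17, 67646372 to 67646506 (1.34-fold), chromosome 1, 24566063 to 24566197 (2.31-fold) and chromosome 2, 22441662 to 22441796 (2.71-fold) and 69156388 to 69156522 (2.55-fold). Over knockout, the chromosome 9 peak was 2.12-fold in males and 3.31-fold in females, and the chromosome 17 peak 2.15-fold and 3.1-fold. These male values lie near the 2-fold limit of the call, so the knockout library was itself high there. The chromosome 1 peak was 2.07-fold over its surroundings in males and 2.06-fold in females, also near the limit.

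The largest male-to-female ratio above the median height was at chromosome 16, 31413929 to 31414063 (4.30-fold, 2.32 to 8.46), then at chromosome 1, 171368180 to 171368314 (3.52-fold), chromosome 4, 53406119 to 53406253 (3.42-fold), chromosome 19, 10371944 to 10372078 (3.31-fold) and chromosome 14, 117651850 to 117651984 (3.30-fold). The smallest was at chromosome 16, 11570080 to 11570214 (0.678-fold, 0.329 to 1.34), then at chromosome 9, 108710924 to 108711058 (0.704-fold), chromosome 16, 91262439 to 91262573, chromosome 8, 17290580 to 17290714 (both 0.811-fold) and chromosome 11, 75389650 to 75389784 (0.823-fold). The intervals of these 5 smallest ratios all included 1.

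The tallest female peaks without a male partner were far above any male one. They lay at chromosome 12, 97457264 to 97457402 (1813.2 normalized tags, 12.2-fold over knockout), chromosome 18, 90736501 to 90736639 (1654.5, 3.23-fold), chromosome X, 165433472 to 165433610 (1585.1, 3.32-fold) and 165556281 to 165556419 (1018, 3.48-fold), and chromosome 11, 121798468 to 121798604 (1190.8, 3.24-fold). The deposited knockout tags at these places were 539, 1863, 1738, 1065 and 1345, in the same order, so the knockout library was itself high there. Whether the male library had signal at these places that failed the knockout rule was not tested. In males the tallest peak without a female partner was at chromosome 1, 24568728 to 24568862 (212.2 normalized tags, 3.86-fold over knockout), 169 bp from a female peak. That peak was only 2.58-fold over its surroundings, where the call asked for 2-fold. The next were at chromosome 6, 47610600 to 47610734 (66.5) and 47701631 to 47701765 (43.6), chromosome 13, 99589668 to 99589802 (51.2) and chromosome 8, 20439137 to 20439271 (33.6).

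The chromosome 6 peaks belong to a cluster that was singled out after its values were seen. Among peaks of at least 20 normalized tags, males had 16 there and females 13. Neighbouring centres lay 4 to 5 kb apart at 8 of 15 steps in males and 9 of 12 in females, with medians of 4332 and 4329 bp. Medians over the knockout were 2.35-fold in males and 2.64-fold in females. FCCP-treated cells had no peak of this height in the stretch and untreated cells had 1, at 4.02-fold over its surroundings. The cell lists asked for 4-fold over the surroundings. The BAT peaks of the cluster were 2.17- to 6.7-fold over theirs in males and 3.3- to 5.86-fold in females. The call rule may thus account for part of the difference from cells, which was not tested.

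**Figure D3:**
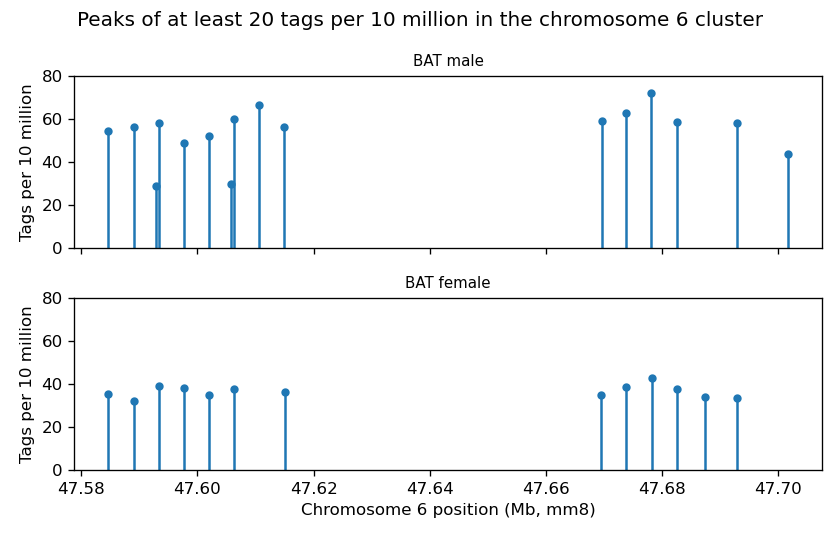
Peaks of at least 20 normalized tags (vertical axis) by position on chromosome 6 (Mb, mm8) in male and female BAT, each line and point being 1 peak. The 16 male and 13 female peaks fall mostly near the same places, many of them at even steps.

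The last comparison sets tissue against cells. Of male BAT peaks, 2048 of 39978 overlapped a peak of either 3T3-L1 list (5.12%, 4.91 to 5.34), and of female peaks 1122 of 19122 (5.87%, 5.54 to 6.21). Circular shifts gave 1.40% and 1.42%. With BAT peaks at least 4-fold over knockout and cell peaks at least 8-fold over their surroundings, the shares were 0.428% and 0.475%, and with equal numbers of top-scoring peaks 3.56% and 3.04%. The circular values belong to the full lists and cannot be set against these shares. At the stricter folds the untreated list held only 3956 peaks and the FCCP list 6371, so chance overlap is lower there, and no value of it is given. Over the full lists, 745 female BAT peaks overlapped an FCCP peak and 701 an untreated peak, and for male BAT the numbers were 1369 and 1220, the FCCP list being the longer one. The order turned when the FCCP list was limited to its top-scoring peaks and set against the whole untreated list. At equal lengths of 44505 peaks, female BAT peaks were met by 603 of the top-scoring FCCP peaks and 701 untreated peaks (Fisher's exact test, two-sided, p = 0.00679, Benjamini-Hochberg adjusted 0.0136 over 2 tests). With male BAT they were 1138 and 1219 (Fisher's exact test, p = 0.0949, adjusted 0.0949). The FCCP and untreated lists share peaks, so these tests overstate independence, and they compare lists rather than conditions. Relative to circular shifts, male BAT overlapped the full untreated list at 4.30 times chance and the full FCCP list at 3.65 times. For female BAT the values were 5.16 and 4.06 times. The FCCP list thus led only in raw counts, where it was the longer one. With 1 list per condition, neither condition is shown to be nearer to BAT. Of the male peaks with a female partner, 28 overlapped peaks of both 3T3-L1 lists.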

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

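All tests here were chosen after the lists had been seen. Those of the raised FCCP thresholds, the 4-fold rule in BAT, the separate chromosomes and the top-scoring peaks had predictions written before their results were known. Tests of the median ratio at shared peaks, of local tags around peaks and of fold ranges picked from the peaks themselves had also gone with their explanations and are not relied on, since the first did not ask whether the shift was large enough and the outcome of the others was largely set by the call rule or the choice of peaks.

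Peaks on the mitochondrial genome entered no comparison. The female list had 9 of them and the male list 3, each at least 2-fold over the knockout library, as the call rule required. The highest fold over knockout was 12.22 in females, at 15602 to 15740 with 2783.5 normalized tags, and 3.41 in males, at 4878 to 5012 with 606.9. Neither 3T3-L1 list contained one.

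More peaks were called after FCCP, 1.36 times the untreated number. Neither deeper sequencing nor a lower tag threshold accounts for it. The FCCP pool had 0.899 times the tags, and its tag threshold was 1.03 times as high relative to the library size. Putative peaks before the filters numbered 287000 for FCCP and 274316 for untreated cells. The local filter then removed 78.9% and 83.7% of them, so the ratio of 1.36 arose largely at that step. Whether the smaller depth of the FCCP pool let more peaks pass this filter was not tested. A slightly higher enrichment of the whole pool may be enough: with both FCCP thresholds raised 1.06-fold, the shift at the tallest 10% of shared peaks, the FCCP list fell to 0.764 times the untreated one. That overshoot shows how steeply the number depends on the thresholds, so the test could hardly have excluded this explanation and leaves it open. More GPS2 on chromatin after FCCP, as the design would have it, remains open and untested without replicates.

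Over 1 Mb windows, male BAT and FCCP peak counts ran opposite (Spearman's rho -0.482 across 2578 windows, which are not independent), while untreated and FCCP counts went together (0.924). Within single chromosomes the median was -0.634, which argues against copy number of whole chromosomes. Holding BAT to the 4-fold local rule left -0.470. The lower quartile of male peaks was already 4.92-fold over the surroundings, so this rule removed few of them. The test could hardly have changed the relation and does not decide on the fold rule alone. Over 3T3-L1 peaks with at least 4 times the expected tags, which can pass the local rule at average background, the relation was gone (0.0224, with 0.668 between the cell lists), so the local filter of the cell lists may carry it by favouring weaker peaks where the background is low. Whether weak peaks do so by themselves stays open: it was also gone among equal numbers of top-scoring peaks (0.0464), but stronger with cell peaks at least 8-fold over their surroundings (-0.646). Tissue against cell line, a difference of the design, stays open as untested.

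In the female list, 58 peaks had at least 100 normalized tags and at least 50-fold over their surroundings, limits chosen after these peaks had been seen. Their median fold over knockout was 3.33 with quartiles of 3.17 and 3.44, and 57 of them overlapped a 3T3-L1 peak and 2 a male BAT peak. The 3T3-L1 lists were called without a control. The deposited knockout tags of the 58 peaks had a median of 404.5 and were at least 148, so signal at these places was not confined to wild-type tissue. The spread of the log2 fold was 1.01 times counting error by the quartiles but 3.09 times by the SD of all 58, so one shared source of reads placed at many positions is left open, and at most for part of them. The median fold lies within the wide range of the female mitochondrial peaks, 2.17 to 12.22, so mitochondrial reads at nuclear copies cannot be told apart from nuclear binding without the sequence of these places. Sex, a difference of the design, stays open as untested.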

How the results depend on the processing

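The ratios of peak numbers and the window correlations, with their alternatives, the alternatives that omit part of chromosome 1 and the shifts of 10 to 100 kb were chosen after seeing the data. No paired analysis was possible because each condition has 1 list. The planned promoter and gene list results, with their alternatives, were not run for want of an annotation on the build of the files. A share or median counted as moved outside the 95% interval of its main value, which is narrow here, and a ratio of peak numbers beyond 1.5 times. By these limits 16 alternative values of the overlap shares, the median ratio and the added ratios of peak numbers did not move, 22 moved and 1 reversed; the cause was not tested except where stated. With peak centres within 200 bp, untreated in FCCP was 40.1%, FCCP in untreated 29.6%, male in female 4.11% and female in male 8.59%. With 50% of the shorter peak covered, which asks for more overlap, these were 36.9%, 27.2%, 2.70% and 5.65%, and BAT in either 3T3-L1 list was 4.42% for males and 5.10% for females. With stricter folds, FCCP in untreated was 25.9%, male in female 1.80%, female in male 3.23%, and BAT in 3T3-L1 0.428% and 0.475%. With equal numbers of top-scoring peaks, untreated in FCCP was 38.9%, FCCP in untreated 39.0%, male in female and female in male both 9.95%, and BAT in 3T3-L1 3.56% and 3.04%. Relative to the tallest 10%, the median log2 ratio of shared FCCP peaks was -0.0105; this only subtracts the median log2 ratio of those pairs, 0.09, from all pairs. The ratio of male to female peak numbers rose to 7.72 at 5 or more normalized tags, and how far the different depth of the libraries contributes was not tested. It was 1.79 at 4-fold over knockout, and that of FCCP to untreated was 1.61 at 8-fold over the surroundings. The window correlation of male BAT with FCCP turned to 0.0464 among top-scoring peaks and 0.0224 over cell peaks with 4 times the expected tags, and was stronger with cell peaks 8-fold over their surroundings (-0.646), within chromosomes (-0.634) and on autosomes alone (-0.543). Against shifts of 10 to 100 kb, which keep regional density, chance overlap was 2.08% for untreated in FCCP and 0.726% for female in male, above the circular values, but 0.925% for male and 1.06% for female BAT in either 3T3-L1 list, below them. How far counting error near the thresholds lowers the overlaps was not tested.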

Other observations

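The values here were looked up after the lists had been seen. The X chromosome held 4.48% of untreated, 5.15% of FCCP, 0.810% of male BAT and 2.09% of female BAT peaks. The sexes are those of the sample labels. The median local tag density around X peaks was 0.883 times the autosomal median in untreated and 0.908 times in FCCP-treated cells.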
